A study of Oryza sativa with 27 samples.

How the data were processed

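The series measured polyA RNA by sequencing in cell suspension cultures of rice (Oryza sativa, cultivar Tsukinohikari) dosed with the herbicide safeners metcamifen or cyprosulfamide at 5 µM, or with the carrier DMSO. Safeners are compounds applied with a herbicide to reduce its injury to the crop. Cells were taken 30, 90 and 240 min after dosing, with 3 biological replicates for each of the 9 combinations of treatment and time, 27 libraries in all. Each library was placed in its group by the treatment, time and replicate number that its labels give.

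The authors deposited 1 table of read counts per locus and library, whole numbers that were not normalized; the unit was checked from the values, whose totals differ between libraries. The submitters' processing notes name GSNAP and edgeR, without versions. The genome build, the annotation, the treatment of reads that match several loci and the use of strand are not given in the sources used here. Counts of loci with near-identical copies, or of overlapping or antisense loci, are therefore uncertain, which applies to every locus named.

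The table holds 46102 loci, of which 45866 carry identifiers that begin with LOC_Os and 236 carry other identifiers. None of the identifiers matched the gene table of the rice reference (39387 rows, assembly ASM3414082v1), which was searched by locus tag, older tag, synonym, symbol, Ensembl identifier and RefSeq transcript: 0 matched. The files do not pair the identifiers with gene names, so no gene name or function is given, and none of the 46 gene lists that had been fixed could be built or tested. Without names, the fixed rule allows at most 2 loci that rose and 2 that fell, and it was read as applying to each comparison. These are the loci with the largest positive and negative log2 fold changes among those with an adjusted p under 0.05, a mean of at least 1 CPM (a count scaled by the TMM-adjusted library total) over the libraries compared, and no overlap between the libraries of the groups. The chromosome of a locus is taken from its identifier only to order loci, as no coordinates were used.

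Loci with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 26465 loci. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model (glmQLFit, glmQLFTest, edgeR 4.0.16 in R 4.3.3). The fit held 9 group means over the 27 libraries, which leaves 18 residual degrees of freedom. It took the libraries as independent, although same-numbered DMSO libraries correlated at 0.37 to 0.83 over the times and metcamifen libraries at 0.27 to 0.75. For comparisons between treatments, adjusted p may therefore be too small and call counts too high. For changes over time in DMSO or in the metcamifen effect, adjusted p may instead be too large and call counts too low. Calls are loci with a Benjamini-Hochberg adjusted p under 0.05, two-sided, adjusted within each of 14 contrasts. Of these, 12 were chosen before the data were examined and 2, the changes of the metcamifen effect from 30 to 90 min and from 90 to 240 min, were added afterwards. Standard errors were taken from the fold change and its F statistic, and can come out too small where the fold change is near 0. CPM are given as mean ± SD over the 3 libraries of a group. A fold against a group without a single count is a lower bound, computed from the counts of each group pooled over its 3 libraries (not from the mean CPM) against a floor of 3 counts over the group, and covers counting error only. Log2 CPM for component analysis, scores and correlations used a prior count of 2.

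Library totals ranged from 5516373 to 43747251 counts. Among 26465 loci simulated from the real means, library sizes and dispersions, with 50 loci changed by each fold size, the test recovered 84% of 2-fold changes for metcamifen against DMSO at 30 min, 90% at 90 min and 84% at 240 min. For cyprosulfamide against DMSO it recovered 80%, 82% and 78% of 2-fold changes, and 50%, 44% and 42% of 1.5-fold changes, at the same times. These simulations draw every library independently. Each held 50 changed loci at each of 1.5-, 2-, 4- and 8-fold, and the cutoff for an adjusted p loosens as more loci change. In a contrast with few changed loci, recovery of 1.5- and 2-fold changes would be lower, and it was not measured. The changed loci were drawn only from those with a DMSO mean of at least 1 CPM, so recovery at lower levels was not measured.

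Whether replicate numbers pair libraries was checked from the correlation of their deviations from the group means, over loci with a mean log2 CPM above 3. Same-numbered DMSO libraries of different times correlated at 0.37 or more, and same-numbered metcamifen libraries at 0.27 or more, so the numbers were taken to pair the times within these treatments. Between metcamifen and DMSO of one time, same-numbered libraries correlated at -0.31 or below, and they were not paired. Cyprosulfamide and DMSO libraries of one number passed the minimum of 0.1 in all 3 pairs at 240 min only, and cyprosulfamide libraries only between 90 and 240 min. No replicate pair agreed within sampling noise: the chi-square per degree of freedom lay between 2.67 and 42.9, and none was a repeat of another.

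Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, no filter, a fit to the compared groups alone, the replicate number as a block, a minimum change of 2-fold, and each library left out in turn. Alternatives chosen after seeing the data were 1 surrogate variable (sva 3.50.0), a block for each treatment and number, all libraries thinned to the smallest, and leaving out 4 libraries in doubt. These were Cyprosulfamide_30min replicate 2 (the deepest), Cyprosulfamide_240min replicate 1 (the shallowest), Metcamifen_30min replicate 1 (7278921 counts) and Metcamifen_240min replicate 3, in which 1 locus took 1.29% of counts.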

Results

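Transcript levels were measured in rice suspension cells 30, 90 and 240 min after a 5 µM dose of metcamifen or cyprosulfamide, or after the carrier DMSO, to ask how each safener changes the transcriptome relative to carrier-treated cells. Each of the 9 groups had 3 biological replicates. Totals per library ranged from 5516373 counts (Cyprosulfamide_240min replicate 1) to 43747251 (Cyprosulfamide_30min replicate 2). DMSO libraries held 16716222 to 21620410 counts and metcamifen libraries 7278921 to 26162571. Depth differed between groups, from 23743177 to 43747251 counts in the 3 cyprosulfamide libraries at 30 min and from 5516373 to 14262183 in those at 240 min. The loci are given by the identifiers in the count table, which are not paired with gene names. In a principal component analysis of the 27 libraries, the first component (21% of variance) did not part the treatments: DMSO replicate 1 lay between 23.8 and 44.6 at the 3 times and DMSO replicates 2 and 3 between -45.2 and -17.8, while Metcamifen replicate 1 lay between -44.1 and -21.3. The second component (17.9% of variance) placed every metcamifen library between 17.9 and 54.6, and every DMSO and cyprosulfamide library between -23.3 and -9.87.

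**Figure D1:**
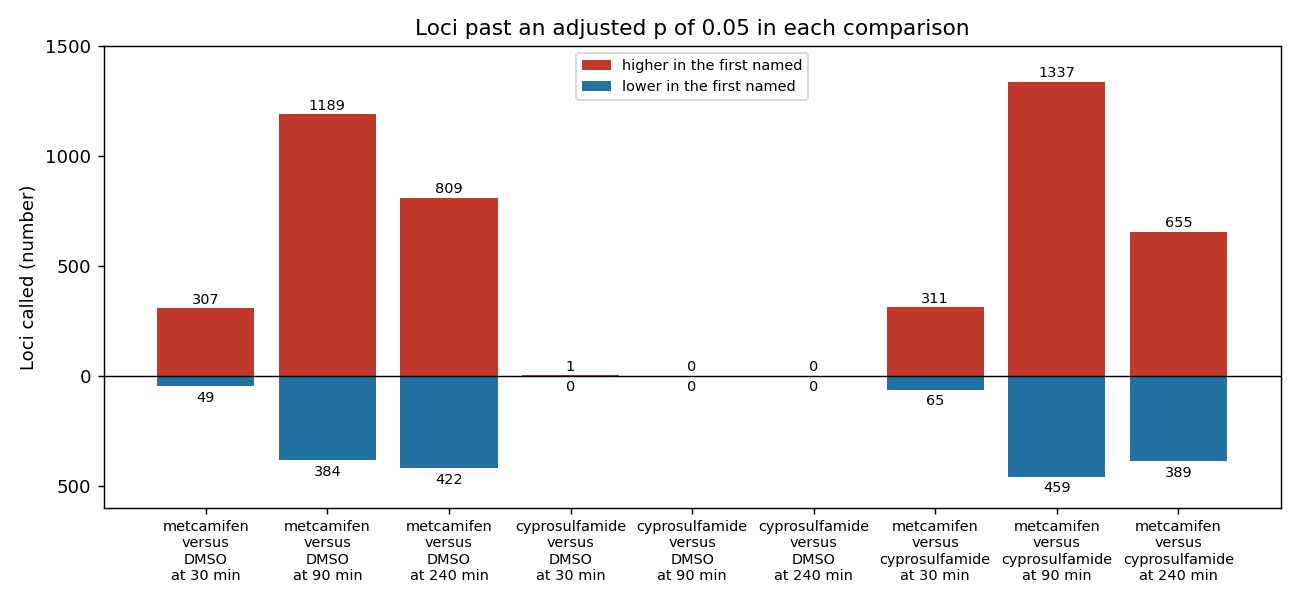
Number of loci (vertical axis) past an adjusted p of 0.05 in each comparison of treatments at 1 time, drawn upward where the level was higher in the treatment named first and downward where it was lower. Metcamifen gave 307, 1189 and 809 higher loci against DMSO at the 3 times, and cyprosulfamide 1, 0 and 0.

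At 30 min, metcamifen raised 307 loci and lowered 49 against DMSO. LOC_Os09g32000 rose from 0.0941 ± 0.0902 CPM to 31 ± 2.72 CPM (SD, n = 3), a log2 fold change of 8.26 (SE 0.41, adjusted p = 5.81e-12 in edgeR's quasi-likelihood test). LOC_Os09g31990 had 0 counts in the DMSO libraries and 2.02 ± 0.294 CPM under metcamifen (112 counts), at least 37.7-fold higher from the pooled counts. LOC_Os03g45250 fell from 3.56 ± 1.74 to 0.543 ± 0.141 CPM (log2 fold change -2.81, SE 0.598, adjusted p = 0.00974), and LOC_Os06g05000 from 4.86 ± 2.57 to 0.782 ± 0.788 CPM (log2 fold change -3.11, SE 0.745, adjusted p = 0.0296). Of the 356 changed loci, 221 changed by at least 2-fold, and 16 rose at least 16-fold. The 307 raised loci took 1.12 ± 0.0594% of all counts in DMSO libraries and 2.58 ± 0.048% in metcamifen libraries. The loci were chosen in these same libraries, so part of such a gap comes from the choice, here and at the later times. Both falls depended on single libraries, and that of LOC_Os06g05000 on other settings too. Its call ended in 7 of 14 alternative settings, with adjusted p from 0.00156 to 0.35. Among these were the omissions of Metcamifen_30min replicate 2 or 3 or DMSO_30min replicate 1 or 3. The call of LOC_Os03g45250 ended without Metcamifen_30min replicate 2 or 3 or DMSO_30min replicate 3, with adjusted p from 0.000472 to 0.116. The log2 fold change of LOC_Os09g32000 was 8.97 without DMSO_30min replicate 2 and ranged from 7.74 to 10.4 over 14 alternative settings. That of LOC_Os06g05000 was -3.86 without Metcamifen_30min replicate 1, and 1 surrogate variable gave 560 calls in all.

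At 90 min, 1189 loci were higher and 384 lower under metcamifen. LOC_Os01g08440 rose from 0.242 ± 0.187 to 109 ± 8.63 CPM (SD, n = 3), a log2 fold change of 8.77 (SE 0.271, adjusted p = 4.83e-17, edgeR). LOC_Os09g34260 had 0 counts in the DMSO libraries and 3.28 ± 0.501 CPM under metcamifen (167 counts), at least 57.5-fold higher from the pooled counts. LOC_Os04g56680 fell from 2.16 ± 0.328 to 0.541 ± 0.283 CPM (log2 fold change -1.95, SE 0.332, adjusted p = 0.000272). LOC_Os06g04990 fell from 15.9 ± 10.4 to 3.73 ± 2.39 CPM (log2 fold change -2.07, SE 0.614, adjusted p = 0.0456). At least 2-fold changes were found at 695 loci, and 60 loci rose at least 16-fold. The 1189 raised loci took 4.1 ± 0.161% of counts in DMSO libraries and 9.19 ± 0.124% in metcamifen libraries. The call of LOC_Os06g04990 ended without DMSO_90min replicate 1 or 3 or any 1 of the 3 metcamifen libraries (adjusted p from 0.00581 to 0.291 over 14 settings), with a log2 fold change of -1.48 without DMSO_90min replicate 3. The log2 fold change of LOC_Os01g08440 was 9.51 without DMSO_90min replicate 1, and 1 surrogate variable gave 2672 calls (1889 higher, 783 lower).

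At 240 min, 809 loci were higher and 422 lower under metcamifen. LOC_Os09g20220 rose from 2.43 ± 1.76 to 136 ± 42.4 CPM (SD, n = 3), a log2 fold change of 5.85 (SE 0.35, adjusted p = 3.09e-11, edgeR). LOC_Os01g08440, named above for 90 min, was still higher, at 8.41 ± 0.821 against 0.203 ± 0.0692 CPM (log2 fold change 5.36, SE 0.306, adjusted p = 1.63e-11). LOC_Os04g12720 fell from 25 ± 8.74 to 3.74 ± 1.47 CPM (log2 fold change -2.69, SE 0.457, adjusted p = 0.000452), and LOC_Os04g12970 from 13.4 ± 4.2 to 2.4 ± 0.891 CPM (log2 fold change -2.42, SE 0.483, adjusted p = 0.00255). Only 7 of the raised loci passed 16-fold, and 350 loci changed by at least 2-fold. The raised loci took 3.32 ± 0.0457% of counts in DMSO libraries and 5.61 ± 0.0496% in metcamifen libraries. The number of calls depended on the libraries used: in place of 1231, it was 746 without Metcamifen_240min replicate 2, 386 in a fit to the 6 compared libraries alone and 814 with all libraries thinned to the smallest, while 1 surrogate variable gave 2388. The log2 fold change of LOC_Os09g20220 was 6.45 without DMSO_240min replicate 3.

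**Figure D2:**
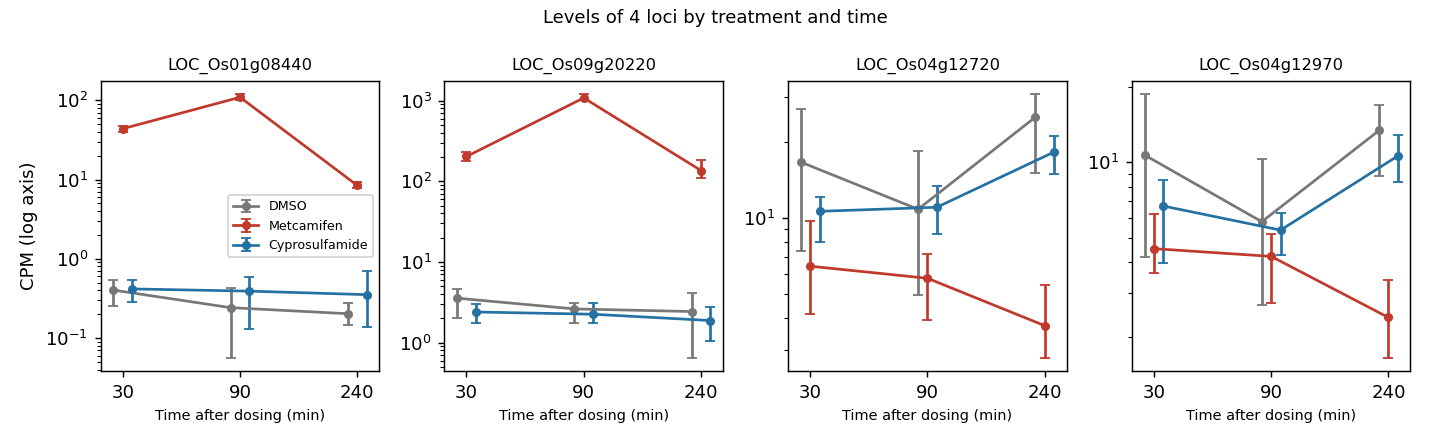
CPM (log axis) of 4 loci against time after dosing, with points at the mean of 3 libraries and bars from the lowest to the highest library. LOC_Os01g08440 and LOC_Os09g20220 had their highest means under metcamifen at 90 min, at 109 and 1080 CPM. LOC_Os04g12720 and LOC_Os04g12970 had 3.74 and 2.4 CPM under metcamifen at 240 min against 25 and 13.4 CPM in DMSO.

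The response to metcamifen changed with time. LOC_Os09g20220 stood at 203 ± 23.6 CPM at 30 min, 1080 ± 98.8 CPM at 90 min and 136 ± 42.4 CPM at 240 min under metcamifen (SD, n = 3), and its effect against DMSO rose by 2.85 log2 units to 90 min (SE 0.486, adjusted p = 0.00115) and then changed by -2.85 (SE 0.508, adjusted p = 0.00176). LOC_Os09g32000 stood at 31 ± 2.72, 13.8 ± 0.609 and 0.862 ± 0.128 CPM, but its effect did not pass the test of a change between any of the times (adjusted p = 1 from 30 to 90 min, 0.0954 from 90 to 240 min and 0.0931 from 30 to 240 min). Its DMSO libraries held only 5, 2 and 4 counts in all at the 3 times, so that test says little on the fall of its level under metcamifen. The effect on LOC_Os01g08440 changed by 2 log2 units from 30 to 90 min, which did not pass (SE 0.543, adjusted p = 0.0621 in edgeR). Its change of -3.41 from 90 to 240 min did pass (SE 0.675, adjusted p = 0.00517). None of these tests of single loci used the pairing of the times, so a failed one does not show an unchanged effect. Of the 307 loci raised at 30 min, 288 were also raised at 90 min, where independent lists would share 13.8. At 240 min 169 of the 307 were also raised, where such lists would share 9.38. The 809 loci raised at 240 min shared 422 with those at 90 min. In all, 1593 loci were raised at 1 or more times and 167 at all 3, and 798 were lowered at 1 or more times and 3 at all 3. The metcamifen libraries of each time were compared with their own DMSO libraries, so no library enters 2 lists. Same-numbered libraries still correlated over the times, at 0.37 to 0.83 in DMSO and 0.27 to 0.75 in metcamifen. The lists are therefore not independent, and the numbers that independent lists would share are no valid chance level. The median log2 change of the loci raised at 30 min was 1.38 at 30 min, 1.98 at 90 min and 0.77 at 240 min. It was the same with the 2 loci at 0 counts in DMSO set to their lower bound. For the loci raised at 90 min it was 0.18, 1.01 and 0.373, and for those raised at 240 min 0.137, 0.526 and 0.766. Each set was chosen at its own time, which raises its median there. Direct tests of the change in effect (edgeR) called 448 loci between 30 and 90 min (401 with a more positive effect at 90 min), 510 between 90 and 240 min (374 more negative at 240 min) and 352 between 30 and 240 min (203 more positive, 149 more negative). With each treatment and replicate number as a block, which the pairing within treatments allows, the 3 counts became 1484, 1646 and 1002, and every locus of the unblocked calls was among them. With all libraries thinned to the smallest they fell to 278, 334 and 210, and with 1 surrogate variable they were 890, 1149 and 915. Fits to the 12 compared libraries alone called 198 loci for the change from 30 to 240 min, and without Metcamifen_240min replicate 2 the count from 90 to 240 min was 334.

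Cyprosulfamide at the same dose gave 1 call at 30 min, 0 at 90 min and 0 at 240 min against DMSO in edgeR's quasi-likelihood test. The locus at 30 min, LOC_Os08g31510, rose from 4.79 ± 0.254 to 9.59 ± 2.67 CPM (SD, n = 3; log2 fold change 1.01, SE 0.158, adjusted p = 0.041). It lost its call in 9 of 14 alternative settings, with adjusted p from 0.000402 to 0.936, among them each omission of 1 library of the 6 other than Cyprosulfamide_30min replicate 3. DESeq2 called 56 loci at 30 min (54 higher), 0 at 90 min and 0 at 240 min. An unadjusted p under 0.05 was reached by 2548, 818 and 1669 of 26465 loci at the 3 times. The 95% interval of the change lay within 2-fold in either direction for 85.1% of loci at 30 min, 85.2% at 90 min and 81.4% at 240 min. These shares include loci without counts in either group, such as LOC_Os09g31990, where the interval shrinks to nothing and carries no information. Standard errors can also come out too small where the change is near 0, so the shares may be too high. The change of the cyprosulfamide effect from 30 to 240 min gave 0 calls in edgeR and 0 in DESeq2, with 816 loci at an unadjusted p under 0.05. At 30 min the count was 50 without the low-count filter, 81 with 1 surrogate variable and 109 without Cyprosulfamide_30min replicate 3, but 0 without any 1 of the 5 other libraries or with the replicate number as a block. At 240 min it was 2 without DMSO_240min replicate 1 and 4 without DMSO_240min replicate 2.

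Metcamifen and cyprosulfamide are both acyl sulfonamides built on a 2-methoxybenzoyl benzenesulfonamide, and differ in the group opposite the sulfonyl on the second ring, a methylureido group in metcamifen and a cyclopropylcarbamoyl group in cyprosulfamide. At the same dose, the direct contrast of both called 376 loci at 30 min (311 higher under metcamifen, 65 lower), 1796 at 90 min (1337 and 459) and 1044 at 240 min (655 and 389). At 30 min LOC_Os09g31990 had 0 counts under cyprosulfamide and was at least 64.1-fold higher under metcamifen, and LOC_Os09g32000 was higher by 8.07 log2 units (SE 0.373, adjusted p = 1.37e-12). That value rests on 10 counts under cyprosulfamide, 9 of them in 1 library, and was 10.1 without Cyprosulfamide_30min replicate 2. LOC_Os02g32420 was lower, at 4.43 ± 0.542 against 12.6 ± 2.84 CPM (log2 difference -1.51, SE 0.194, adjusted p = 1.19e-05), as was LOC_Os03g45250, at 0.543 ± 0.141 against 2.55 ± 0.876 CPM (log2 difference -2.35, SE 0.596, adjusted p = 0.0469). The call of LOC_Os03g45250 ended without any 1 of the 3 metcamifen libraries or Cyprosulfamide_30min replicate 1 or 2 (adjusted p from 0.00545 to 0.296 over 14 settings). At 90 min LOC_Os09g20220 stood at 1080 ± 98.8 CPM under metcamifen and 2.25 ± 0.718 CPM under cyprosulfamide (log2 difference 8.85, SE 0.385, adjusted p = 2.29e-14), next to 2.62 ± 0.738 CPM in DMSO. LOC_Os09g32000 was at least 211-fold higher under metcamifen at that time. LOC_Os06g08340 was lower, at 2.87 ± 0.972 against 10.9 ± 1.83 CPM (log2 difference -1.89, SE 0.297, adjusted p = 9.52e-05), as was LOC_Os02g56920, at 1.2 ± 0.168 against 4.45 ± 0.219 CPM (log2 difference -1.86, SE 0.449, adjusted p = 0.0097). At 240 min LOC_Os03g57200 was higher by 5.02 log2 units (SE 0.255, adjusted p = 5.22e-12), at 16.7 ± 2.11 against 0.513 ± 0.0295 CPM, and LOC_Os10g24690 was lower by a log2 difference of -2.27 (SE 0.309, adjusted p = 3.84e-05), at 2.27 ± 0.508 against 10.6 ± 2.6 CPM. LOC_Os09g20220 was also higher at 240 min (log2 difference 6.10, SE 0.391, adjusted p = 1.64e-10) and LOC_Os04g12720 lower (log2 difference -2.26, SE 0.469, adjusted p = 0.00469).

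Of the loci that metcamifen changed against DMSO, 290 of 356, 1300 of 1573 and 760 of 1231 also differed from cyprosulfamide in the same direction at 30, 90 and 240 min, although both contrasts use the same metcamifen libraries, which favours a shared direction. The loci raised by metcamifen took 1.13 ± 0.0332%, 4.12 ± 0.097% and 3.52 ± 0.0342% of counts in cyprosulfamide libraries at the 3 times (SD, n = 3), next to 1.12 ± 0.0594%, 4.1 ± 0.161% and 3.32 ± 0.0457% in DMSO libraries. At these loci the median log2 change under cyprosulfamide was 0.06, 0.01 and 0.10. By the test, the safeners did not differ at 26089, 24669 and 25421 loci at the 3 times. The 95% interval of the difference lay within 2-fold in either direction for 84.6%, 82% and 79.8% of these. Loci without counts in both groups would again count as within 2-fold, and standard errors that are too small near 0 may again raise the shares. The count at 240 min was 665 without Cyprosulfamide_240min replicate 1, 681 without Metcamifen_240min replicate 1 and 603 without the 4 libraries in doubt, and 1 surrogate variable gave 617, 2964 and 1727 calls at the 3 times.

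**Figure D3:**
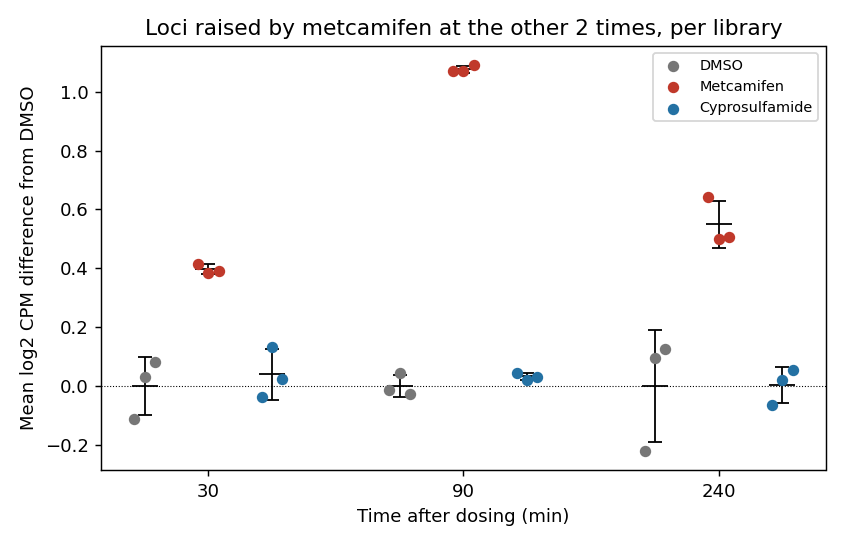
Mean difference in log2 CPM from the DMSO mean of the same time (vertical axis) for each library, over the loci that metcamifen raised at the other 2 times, against time after dosing, with bars for the mean and SD of 3 libraries. Metcamifen libraries averaged 0.397, 1.07 and 0.549 and cyprosulfamide libraries 0.0388, 0.0323 and 0.00304.

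A score per library was formed from loci raised by metcamifen at the other 2 times, so that each time was scored on loci called in other libraries. These are not independent of the scored ones, since same-numbered libraries over the times correlated at 0.37 to 0.83 within DMSO and 0.27 to 0.75 within metcamifen. Metcamifen libraries scored 0.397 ± 0.017 log2 units above DMSO at 30 min (1576 loci), 1.07 ± 0.01 at 90 min (947 loci) and 0.549 ± 0.081 at 240 min (1208 loci; SD, n = 3). Cyprosulfamide libraries scored 0.0388 ± 0.085, 0.0323 ± 0.012 and 0.00304 ± 0.06. In exact two-sided permutation tests against DMSO (n = 3), metcamifen reached p = 0.1 at each time, which is the smallest that 3 against 3 libraries allow, and cyprosulfamide gave p = 0.7, 0.3 and 1.

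Fold changes of both safeners against the same DMSO libraries were correlated across 26465 loci with r = 0.419 at 30 min, 0.197 at 90 min and 0.426 at 240 min; loci are not independent replicates. Unchanged groups simulated with shared controls gave 0.499 ± 0.01, 0.48 ± 0.0092 and 0.424 ± 0.0089 (SD over 20 simulations). Both treated groups were drawn from the DMSO means, so all simulations here hold no metcamifen response. Such a response widens the spread of its fold changes and can lower r by itself. An r below the simulated one is therefore no evidence against a shared response. The covariance was 0.0371, 0.0197 and 0.0459, next to 0.0299, 0.0297 and 0.029 in the simulations and to 0.0328, 0.0306 and 0.045 from the variance of the DMSO means. Calls shared by both safeners against DMSO numbered 0 in either direction at each time, where independent lists would share 0.0116 raised loci at 30 min and 0 otherwise. With 3 DMSO libraries per time the controls were not split, since 1 part would hold a single library, and part of any excess may come from the shared controls. Without DMSO replicate 1 of the same time, r was 0.599, 0.33 and 0.645, next to 0.605 ± 0.0088, 0.579 ± 0.0069 and 0.525 ± 0.0065 in unchanged groups simulated with the same 2 controls (SD over 20 simulations, which draw libraries independently).

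**Figure D4:**
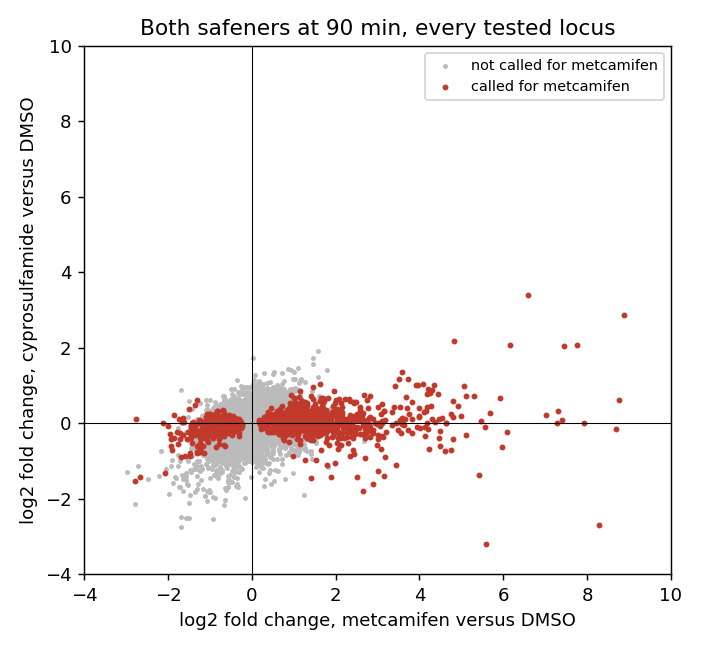
Log2 fold change against DMSO at 90 min under cyprosulfamide (vertical axis) and under metcamifen (horizontal axis) for each of 26465 tested loci, with the loci called for metcamifen in red. The loci raised by metcamifen have a median change of 1.01 log2 units under metcamifen and 0.01 under cyprosulfamide. They were chosen in these metcamifen and DMSO libraries, which raises the first median.

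Carrier-treated cells themselves changed over the sampled time. Between 30 and 240 min, 180 loci rose and 319 fell in DMSO libraries. LOC_Os10g24690 rose from 2.58 ± 0.481 to 8.56 ± 3.81 CPM (SD, n = 3; log2 fold change 1.73, SE 0.292, adjusted p = 0.00178, edgeR) and LOC_Os01g71810 from 0.584 ± 0.175 to 2.31 ± 1.28 CPM (log2 fold change 1.97, SE 0.391, adjusted p = 0.0071). LOC_Os06g05000 fell from 4.86 ± 2.57 to 0.297 ± 0.309 CPM (log2 fold change -4.06, SE 0.78, adjusted p = 0.00537) and LOC_Os03g45250 from 3.56 ± 1.74 to 0.457 ± 0.382 CPM (log2 fold change -3, SE 0.584, adjusted p = 0.00598). With each treatment and number as a block, the pairing raised the count from 499 to 1856, which included all 499. A fit to the 6 compared libraries alone gave 0 calls, ending those of the 4 named loci, and DESeq2 gave 639. The count was 304 without DMSO_30min replicate 2, 179 without DMSO_30min replicate 3, 301 without DMSO_240min replicate 2 and 312 without DMSO_240min replicate 3. It was 245 with libraries thinned and 1573 with 1 surrogate variable. The call of LOC_Os01g71810 also ended without DMSO_240min replicate 2 (adjusted p from 0.000605 to 0.341 over its settings), and that of LOC_Os06g05000 with libraries thinned (adjusted p = 0.0507, from 9.77e-08 to 0.232 over its settings). The log2 fold change of LOC_Os06g05000 was -3.47 without DMSO_240min replicate 2 and -5.04 without DMSO_240min replicate 3, and that of LOC_Os03g45250 was -3.88 without DMSO_240min replicate 3.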

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

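The tests of exchanged or inactive cyprosulfamide cultures, of a larger spread among cyprosulfamide libraries and of 1 culture sampled repeatedly were chosen after the results were seen, as were the contrasts from 30 to 90 and from 90 to 240 min. The effects of the safeners differed from each other in direct tests at 376 loci at 30 min, 1796 at 90 min and 1044 at 240 min. The metcamifen effect differed between times at 352 loci (240 against 30 min), 448 (90 against 30 min) and 510 (240 against 90 min).

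Metcamifen changed 356 loci or more at each time and cyprosulfamide at most 1. Thinning every library to the smallest left 282 or more metcamifen calls at each time, which argues against depth. An exchange of the whole safener groups cannot be told apart from the labelled order, as 0 of the 18 safener libraries scoring nearer the other group on the metcamifen-raised loci is what it would give too. The highest score of a cyprosulfamide library was 0.329 of the metcamifen mean (Cyprosulfamide_30min replicate 2). It passed a first bound of 0.25, which was later replaced by the spread of the libraries. This score argues against a response of like size hidden by a larger spread at the metcamifen-raised loci, and does not cover other loci. The SD of the cyprosulfamide scores at 30 min was 0.085, against 0.017 under metcamifen and 0.099 in DMSO. At 90 min it was 0.012, against 0.01 and 0.038, and at 240 min 0.06, against 0.081 and 0.19. Whether cyprosulfamide cultures received active compound cannot be told apart from a weak response: 36 loci were raised at 30 min in DESeq2, without the filter and with 1 surrogate variable, but 0 of them by DESeq2 without Cyprosulfamide_30min replicate 2, and a difference between the compounds, which the design names, stays open too.

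Calls for metcamifen were most numerous at 90 min. With thinned libraries the count at 90 min was 1.35 times the larger of the others (282, 1096 and 814), which argues against depth. Against all 9 DMSO libraries the counts were 541, 2317 and 2789, a ratio of 0.831, so the choice of DMSO libraries may set which time has the most calls. That comparison also counts changes with time that all cultures share, as the DMSO cultures showed at 499 loci. The changes in effect size were tested directly and do not rest on the counts. Those tests also subtract the DMSO libraries of each time, so they cannot set a drift of the DMSO cultures apart from a change under metcamifen.

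Libraries of 1 replicate number deviated together within a treatment. The first component of the deviations from group means (52.3% of their variance) did not follow library size over the 27 libraries. Spearman rho was -0.143 (permutation p = 0.48) and Pearson r -0.0548 (permutation p = 0.79), or -0.0903 without the 2 libraries farthest from the median size. Library size was not centred within groups as the component was, which weakens this test. DMSO replicate 1 was the deepest library of its group at each time, so depth stays open there. Metcamifen replicate 1 was the shallowest of its group at 30 min and the deepest at 240 min, but kept its sign. Cyprosulfamide replicate 1 was the deepest at 90 min (-12.6) and the shallowest at 240 min (-12). This argues against depth in metcamifen and cyprosulfamide. Same-numbered libraries of a treatment correlated above others by 0.681, against at most 0.657 in 10000 shuffles of the numbers (permutation p = 1e-04, the smallest they can give), which restates the pattern: 1 culture sampled at all 3 times cannot be told apart from other causes shared by a number, as the labels name neither. On this component DMSO replicate 1 lay at -22.6, -22.8 and -33 and Metcamifen replicate 1 at 13.6, 15.5 and 21.4 at the 3 times, opposite to the other replicates of each treatment. No biological explanation was tested.

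Other splits of the same libraries, refitted with the other groups kept, bear on each count. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For metcamifen against DMSO the real counts were 356, 1573 and 1231, reached by 1, 1 and 2 of 10 splits, with the highest other split at 0, 0 and 1897. The split with 1897 set DMSO_240min replicate 1 with Metcamifen_240min replicates 2 and 3, which is the division seen on the component above and points to a structure of the samples. For cyprosulfamide against DMSO the real count of 1 at 30 min was reached by 2 of 10 splits, with the highest other at 1, and the real counts of 0 at 90 and 240 min by all 10 splits, as any split reaches 0, with the highest other at 0. For metcamifen against cyprosulfamide the real counts were reached by 1 of 10 splits at each time, with the highest other at 0. For DMSO at 240 against 30 min the real count of 499 was reached by 1 of 10 splits, with the highest other at 238, and at 0 among the 3 others that part all 3 same-numbered pairs.

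For the changes of effect with time, 45 splits within each time were drawn. As many calls came from 10 of them for metcamifen from 30 to 240 min (352, highest other 2177). From 30 to 90 min 5 did (448, highest other 933), and from 90 to 240 min 6 did (510, highest other 3397). Chance is not excluded, but these splits cannot measure it. Some leave the treatments apart at 1 time and so hold the metcamifen effect there. From 30 to 90 min, every other split that reached 448 calls kept the 3 DMSO libraries of 90 min together. For cyprosulfamide the real count was 0, which all 45 splits reach whatever they hold (highest other 74), so they say nothing on chance there. The highest counts from 30 to 240 min (2177) and from 90 to 240 min (3397) came from splits that set DMSO_240min replicate 1 with Metcamifen_240min replicates 2 and 3. That is the division named above for 240 min. Among the 9 other splits that keep same-numbered libraries of a treatment together, the highest was 0 for each of the 4.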

How the results depend on the processing

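Alternatives with 1 surrogate variable, thinned libraries, 4 libraries left out and a block within treatments were chosen after seeing the data. Of 272 values of comparison counts and correlations under alternatives, 209 stayed within the margin (1.5 times for counts, 1 SD of the leave-one-out values for correlations), 63 moved and 0 reversed. Of 409 values of named loci, 370 kept direction and call, 39 kept direction and lost the call (23 with 1 library left out, 16 otherwise) and 0 reversed. The cause was not tested for any of the moved values, except that fewer libraries or counts entered where stated. TMM and RLE factors differed by at most 0.0109 log2 units, and RLE moved no count by over 1.5 times.

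Requiring a 2-fold change gave 221, 695 and 350 calls for metcamifen against DMSO at 30, 90 and 240 min, 225, 712 and 266 for metcamifen against cyprosulfamide, 177, 254 and 286 for the change of the metcamifen effect from 30 to 240, 30 to 90 and 90 to 240 min, and 116 for DMSO over time. With 1 surrogate variable these were 560, 2672 and 2388, then 617, 2964 and 1727, then 915, 890 and 1149, and 1573, and cyprosulfamide against DMSO gave 81 at 30 min and 1 at 240 min. With libraries thinned to the smallest (fewer counts), metcamifen at 240 min gave 814, its changes of effect 210, 278 and 334, DMSO over time 245, and cyprosulfamide at 30 min 0. In fits to the compared groups alone (fewer libraries), metcamifen at 240 min gave 386, its change from 30 to 240 min 198, DMSO over time 0, and cyprosulfamide at 30 min 0. Without the 4 libraries in doubt, metcamifen against cyprosulfamide at 240 min gave 603 and cyprosulfamide at 30 min 0. Cyprosulfamide at 30 min gave 56 calls in DESeq2 and 50 without the filter, and the correlation of the safeners at 90 min was 0.278 without the filter.

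The replicate block across treatments took cyprosulfamide at 30 min from 1 call to 0 and changed no other call count by over 1.5 times (346, 1549 and 1219 for metcamifen). These numbers do not pair metcamifen with DMSO, where 0 of 6 libraries correlated best with their own number at 30 min. The block leaves the correlations as they were, because the design is balanced. With a replicate block within treatment, the metcamifen changes gave 1002, 1484 and 1646 calls and DMSO over time 1856, while the cyprosulfamide change stayed at 0.

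Leaving out 1 library at a time, metcamifen at 240 min ranged from 746 to 1152, cyprosulfamide from 0 to 109 at 30 min and from 0 to 4 at 240 min, metcamifen against cyprosulfamide at 240 min from 665 to 767, DMSO over time from 179 to 581 and the metcamifen change from 90 to 240 min from 334 to 644. The correlations ranged from 0.337 to 0.599 at 30 min, 0.151 to 0.33 at 90 min and 0.348 to 0.645 at 240 min. Where a library was left out, its group kept 2. The planned gene list tests were not run, since no list could be built without gene names. The 240 min cyprosulfamide group had the lowest mean depth of the 9 groups, with 5516373 to 14262183 counts.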

Other observations

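The test of a weak shared response and the set of 36 loci were chosen after their results were seen. Loci that metcamifen raised, and those that it lowered, were neighbours by identifier more often than in shuffled calls. Neighbours are adjacent among the tested loci, so untested loci may lie between them. Ordered along the chromosomes by identifier, 26377 tested loci held 182 neighbouring pairs raised at 90 min among 1188 raised loci, where shuffled calls gave 53.4 ± 7 (SD over 10000 shuffles; permutation p = 1e-04, the smallest they can give), which argues against chance placement. At 30 min 307 raised loci held 38 such pairs (3.58 ± 1.9 in shuffles), and at 240 min 808 held 80 (24.7 ± 4.9). At 90 min 26 runs of 3 or more neighbours held 85 raised loci. The longest run, of 5 loci on chromosome 6, had log2 fold changes from 1.46 to 6.09 under metcamifen and from -0.228 to 0.047 under cyprosulfamide. Lowered loci held 3 neighbouring pairs at 30 min (0.0844 ± 0.29 in shuffles), 19 at 90 min (5.57 ± 2.3) and 22 at 240 min (6.69 ± 2.5). Neighbouring loci can be copies that share reads, which was not tested.

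The 36 loci raised by cyprosulfamide at 30 min in 3 settings had a mean log2 difference from DMSO of 0.876 ± 0.38 in cyprosulfamide libraries at 30 min, where they were chosen, 0.244 ± 0.13 at 90 min and 0.491 ± 0.14 at 240 min (SD, n = 3). At 240 min the cyprosulfamide libraries lay between 0.33 and 0.602 and the DMSO libraries between -0.213 and 0.204 (exact two-sided permutation p = 0.1, the smallest possible), and at 90 min p = 0.2. The loci were chosen against the DMSO libraries of 30 min, whose same-numbered libraries at 240 min correlated with them at 0.37 to 0.83, so the values at 240 min are not an independent check. Metcamifen libraries had 0.482 ± 0.096 at 30 min, 0.207 ± 0.054 at 90 min and 0.227 ± 0.05 at 240 min.

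A hypothesis that cyprosulfamide weakly raises the loci raised by metcamifen was tested at 240 min, where the median log2 change of the metcamifen-raised loci was 0.10 under cyprosulfamide. On loci chosen at the other 2 times, the cyprosulfamide libraries scored 0.00304 on average, between -0.0636 and 0.0526, and the DMSO libraries between -0.221 and 0.126 (SD 0.19). A shift of 0.10 is smaller than this spread, so the hypothesis stays open. The raised loci of 240 min took 3.52 ± 0.0342% of counts under cyprosulfamide and 3.32 ± 0.0457% in DMSO, but were chosen against the same DMSO libraries.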
